A study of Mus musculus with 32 samples.

How the data were processed

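The samples were 32 tibialis anterior muscles, a fast limb muscle, from Gaa-/- and wild-type (WT) mice labelled as a mix of inbred strains, aged 1.5, 4, 6 or 9 months. Each of the 8 groups of genotype and age held 4 arrays, which the labels call biological replicates and the design statement calls animals. Gaa encodes acid alpha-glucosidase, the lysosomal enzyme that breaks down glycogen and that is deficient in Pompe disease. The sex of the animals was not labelled. Per the labels, about 20 mg of each muscle had been kept in RNAlater before RNA extraction and DNase treatment. From each sample, 100 ng of RNA was labelled with biotin (GeneChip WT Plus) and read on a 1-colour Affymetrix array.

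The deposited values were on the log2 scale, with 1 value per probe set and array. The submitters' processing notes name RMA, a method of background correction, quantile normalization and probe summary, and the R package affy. Their versions, the genome build and any filter are not given in the sources used here. The values ran from 1.387 to 13.79, and the medians of the arrays from 5.665 to 5.818. The standard deviation of the values of an array, called the array spread here, ran from 1.79 to 2.026. Arrays carry no read depth, so the number of arrays limits the precision. Pearson's r across probe sets was 0.9713 to 0.9908 for 2 arrays of a group and at least 0.9416 for any 2 arrays.

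Of the 20079 probe sets, 19291 carried 1 gene symbol in the platform table, 0 carried several and 788 carried none. Each of the 19291 genes had 1 probe set, and all were tested without a filter on dim genes. All 19291 were matched by Entrez number to a RefSeq gene table of assembly GRCm38.p6, with 0 symbols updated. That table served only for gene names and the order of genes, and none of its coordinates is printed. In 5 probe sets the 32 values repeat those of another probe set.

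Computation used R 4.3.3 and limma 3.58.1. A linear model with 1 mean per group was fitted to all 32 arrays with lmFit, followed by contrasts and eBayes (24 residual and 6.93 prior degrees of freedom, median residual SD of a gene 0.228). All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 19291 genes, with a threshold of 0.05. The contrasts were Gaa-/- minus WT at each age, the mean of these 4 differences (called over all ages), and the difference at 9 months minus that at 1.5 months. Moderated F-tests asked whether the genotype difference changed among the 4 ages, and whether a gene changed with age within WT or within Gaa-/-. The direction of an F-test call was taken from 9 minus 1.5 months. Gaa was also compared by an exact two-sided permutation test of 4 against 4 arrays, whose smallest p is 0.0286. Overlaps of the calls at several ages were set against the number given by the product of their shares. Correlations between ages were computed across genes, which are not independent replicates. Genes among the 50 tested genes on each side of Gaa were compared with all other genes by a two-sided Fisher's exact test.

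There were 33 gene lists. They covered lysosomal hydrolases and membrane proteins, V-ATPase subunits, autophagy machinery, glycogen synthesis and breakdown, glycolysis and glucose uptake, oxidative phosphorylation, fatty acid uptake and oxidation, slow fibre genes, fast fibre genes, neuromuscular junction and denervation response, satellite cells and regeneration, muscle atrophy, and proteasome subunits. Further lists held markers of macrophages, MHC class II antigen presentation, T cells, B cells, neutrophils, fibroblasts and fibro-adipogenic progenitors, extracellular matrix, endothelium, smooth muscle and pericytes, Schwann cells, adipocytes, blood cells and tendon. The remaining lists were integrated stress and unfolded protein response, NRF2 and antioxidant response, interferon response, cell cycle, circadian clock, immediate early genes, and calcium handling with excitation-contraction coupling. Each list was tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the 33 lists. Counts of members past the threshold were made over all genes tested and adjusted over the list alone.

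The genes, lists, tests and alternatives were chosen before the data were examined, apart from additions named as such in the closing section. Genes were named by a rule. Gaa was always named. At each age, up to 10 genes with the largest rise and up to 10 with the largest fall were eligible among those past the threshold with no overlap between the 4 Gaa-/- and 4 WT values. Over all ages, the same number was eligible with the same sign at all 4 ages. For the interaction and the 9 minus 1.5 month difference the 10 smallest p-values were eligible, and for age within a genotype the 10 largest changes each way. Each list gave the 4 members with the smallest p over all ages and 2 in every other contrast where the list passed camera. Near Gaa, up to 6 changed genes were eligible. Predicted genes, small RNA genes and sex-linked genes were counted but not named.

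The alternatives were a replicate block, a filter leaving out the 30% dimmest genes, a trended and robust prior, array weights, a second quantile normalization, centring on array medians, all probe sets, a minimum of 1.5-fold, an adjusted p under 0.01, only the samples of an age, and leaving out each sample in turn. For lists they were camera with an estimated correlation, camera on ranks and fry. The mean of several probe sets was void because no gene had several, and Xist as a covariate was not run because Xist was not among the named probe sets. Every count was also compared with other splits of the samples, all 35 for 4 against 4 and otherwise 100 drawn with a fixed seed. The fit was tested on simulated data with 100 genes shifted by each size given here. At 9 months it recovered 34% of shifts of 0.5 log2 units and 93% of shifts of 1 unit with 8 false calls, and over all ages 93% and 100% with 9 false calls. Of 100 random lists, 3 had a camera p under 0.05. Simulated genes varied independently and without differences in array spread, so these rates need not hold for the real arrays.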

Results

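Gene expression in the tibialis anterior of Gaa-/- and WT mice was measured on 32 arrays, 4 for each genotype at 1.5, 4, 6 and 9 months. The comparison asks how loss of acid alpha-glucosidase alters muscle gene expression from young to older adult age. Differences are Gaa-/- minus WT on the log2 scale, given as estimate ± standard error from limma, and folds are computed from them. The median absolute difference between 2 arrays of a group was 0.157 to 0.296 log2 units. No background level was measured here, so folds of genes whose lower group had a mean under the lowest array median (5.665) are best read as lower bounds. Among them were Aqp4 from 4 months on, Mybph at 4 months, Mstn at 9 months, Mt3, Rrad, Klf5, Map1a, Chrnd, Mpeg1, Gsta2 and Mettl21c. Over the 32 arrays, transcripts of the Y-linked genes ran from 7.06 to 8.2 (Eif2s3y), 6.69 to 7.63 (Uty) and 5.16 to 6.44 (Kdm5d). Eif2s3y was lower in WT at 9 months (7.06 to 7.27) than in younger WT (7.48 to 8.20). In Gaa-/- at 9 months it was 7.06 to 7.91. No sex was inferred from these values.

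Gaa, represented by the probe set TC1100001999.mm.2, was lower in every Gaa-/- muscle than in any WT muscle of its age. Its level fell from 10.29 ± 0.19 in WT to 6.605 ± 0.065 in Gaa-/- at 1.5 months (mean ± SD, n = 4 each), a 12.9-fold reduction. At 4 months the level fell from 10.53 ± 0.12 to 6.981 ± 0.25, at 6 months from 10.5 ± 0.14 to 6.767 ± 0.31, and at 9 months from 10.66 ± 0.043 to 6.868 ± 0.043. The folds at 4 and 6 months were 11.7 and 13.3, and the log2 differences were -3.69, -3.55, -3.73 and -3.79 at the 4 ages (SE 0.13). The limma adjusted p-values were 1.45e-19, 4.52e-19, 9.9e-20 and 6.49e-20 from the youngest to the oldest mice. An exact two-sided permutation test gave p = 0.0286 at each age, the smallest that 4 against 4 arrays allow. The part of the transcript that the probe set covers is not given in the sources used here.

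**Figure D1:**
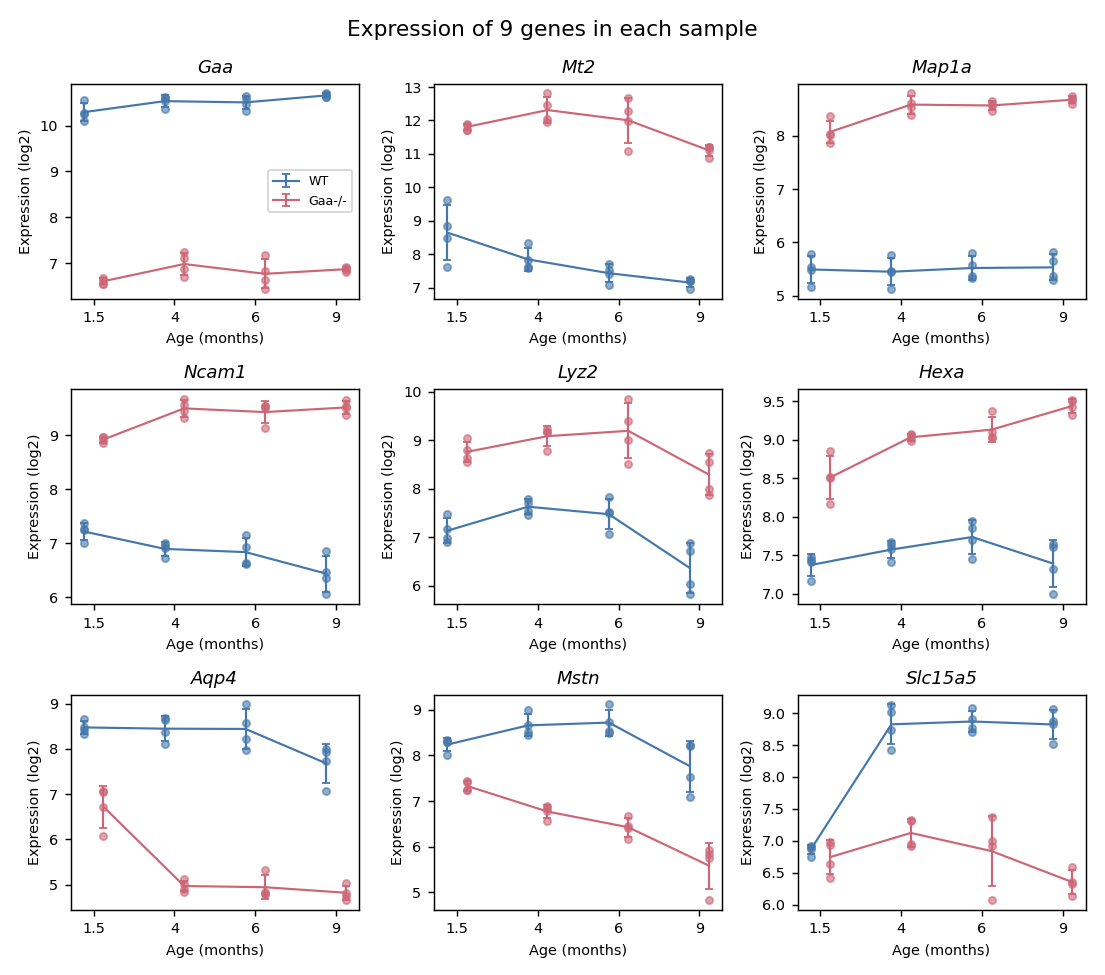
Expression (log2) of 9 genes by age in months, with 1 point per array and lines through the group means with SD (n = 4) in WT and Gaa-/-. Slc15a5 lay between 8.427 and 9.12 in WT muscle from 4 months on and between 6.078 and 7.371 in Gaa-/- muscle from 1.5 to 9 months.

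At 1.5 months, the largest measured rises in Gaa-/- muscle were those of Mt3 and Mt2, which encode metal-binding metallothioneins. The folds of Map1a and Gsta2 are lower bounds, so their true rank against Mt2 is not settled. Mt3 rose 11.9-fold (log2 3.58 ± 0.18) and Mt2 rose 8.92-fold (log2 3.16 ± 0.28). Map1a, a microtubule-associated protein, rose 5.99-fold (log2 2.58 ± 0.14), and Tubb6, a beta-tubulin, rose 3.91-fold. Eda2r, a receptor of the tumour necrosis factor receptor family, rose 5.7-fold, the protease inhibitor Serpinb1a 5.65-fold, the glutathione S-transferase Gsta2 5.58-fold, and Timp1, an inhibitor of matrix metalloproteinases, 3.71-fold. Rasd2, a small GTPase, rose by 2.10 ± 0.23 and AI506816 by 2.20 ± 0.17. Among the genes that fell, the water channel Aqp4 was 3.36-fold (log2 -1.75 ± 0.21) lower. The mitochondrial carrier Slc25a25 changed by -1.52, the mitochondrial enzyme Adhfe1 by -1.57, the angiopoietin-like Angptl7 by -1.56, Tmem100 by -1.56 and Lrrc52 by -1.66. All of these genes separated the 4 Gaa-/- from the 4 WT arrays without overlap, as the naming rule required, with adjusted p from 5.34e-15 (Mt3) to 0.00343 (Lrrc52). In all, 700 of 19291 genes changed, 401 higher and 299 lower, with at least 2-fold rises in 86 and falls in 28.

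Among the gene groups at 1.5 months, the neuromuscular junction and denervation list rose, with 5 members higher and 1 lower of 19 (mean log2 difference 0.393, camera adjusted p = 5.93e-08, and 0.00289 with an estimated correlation). Its member Ncam1, a neural cell adhesion molecule, rose 3.26-fold, and Chrnd, an acetylcholine receptor subunit, rose 3.42-fold. The endothelial list fell (mean -0.216, 1 of 13 lower, adjusted p = 0.0386 with an estimated correlation). That member was Flt1 (-0.41), whose call was lost without 5 of the 8 samples, each left out in turn. Genes of fatty acid uptake and oxidation were lower as a list, with 8 of 22 lower over all genes and 14 lower and 1 higher adjusted over the list alone (mean -0.388, camera adjusted p = 2.16e-11). That list had adjusted p = 0.152 with an estimated correlation. Adipocyte markers had a mean of -0.375 at the same age, with 0 of 9 members past the limma test, camera adjusted p = 0.0192 and adjusted p = 0.398 with an estimated correlation. The lipoprotein lipase gene Lpl, also expressed by adipocytes, changed by -0.81 ± 0.14 and Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain, by -0.61 ± 0.13. Macrophage markers had 7 of 23 members higher (mean 0.542, adjusted p = 0.0946 with an estimated correlation), led by the lysozyme gene Lyz2 at 3.09-fold. Camera called 15 of the 33 lists at this age and 2 with an estimated correlation. Without replicate 1 of Gaa-/- at 1.5 months the count of changed genes was 456.

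At 4 months, the largest measured rise was that of the metallothionein gene Mt2 and the largest measured fall after Gaa that of Aqp4. The folds of Rrad, Mt3, Klf5, Map1a, Mybph and Aqp4 are lower bounds, so their true ranks are not settled. Mt2 rose 22.1-fold (log2 4.47 ± 0.28), Mt3 9.03-fold and Mt1 6.87-fold. Rrad, a small GTPase that inhibits calcium channels, rose 9.45-fold (log2 3.24 ± 0.30), Map1a 8.81-fold, Serpinb1a 8.71-fold, the zinc-finger transcription factor Klf5 7.84-fold, Mybph, which encodes myosin-binding protein H, 6.49-fold, the ceramide synthase Cers6 6.37-fold and Tiam2, an exchange factor for Rac, 6.17-fold. Aqp4 fell at least 11.1-fold (log2 -3.48 ± 0.21), with levels of 4.847 to 5.118 in Gaa-/- muscle. The methyltransferase gene Mettl21c fell 7.77-fold, Mss51 5.44-fold, Mstn, which encodes the muscle growth inhibitor myostatin, 3.7-fold, and Ampd1, the muscle AMP deaminase, 3.4-fold. Cyp4f39 changed by -2.06, the mitochondrial protein gene Gdap1 by -1.81, Gadd45g by -1.76 and the solute carrier gene Slc15a5 by -1.70. Each of these genes showed no overlap between the 4 arrays of either genotype, as the naming rule required, with adjusted p from 2.42e-16 (Map1a) to 0.000654 (Gadd45g). The test called 1099 genes, 656 higher and 443 lower, of which 146 rose and 59 fell at least 2-fold. The calls were 701 higher and 321 lower after median-centring, and 666 higher and 658 lower with the array spread as a covariate.

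Gene groups at 4 months included the neuromuscular list, with 8 higher and 1 lower of 19 (mean 0.587, adjusted p = 0.000201 with an estimated correlation), and Chrnd up 4.17-fold. Macrophage markers rose (11 of 23 higher, mean 0.639), as did the NRF2 and antioxidant list (7 higher and 1 lower of 18, mean 0.386), the atrophy list (5 higher and 1 lower of 14, mean 0.624) and the satellite cell and regeneration list (2 of 18 higher, mean 0.294), each with adjusted p = 0.0472 with an estimated correlation. The atrophy list had a median of 0.223, and its members Mt2 (4.47) and Mt1 (2.78) made up most of its mean. Mpeg1, a macrophage perforin-like gene, rose 3.47-fold and Srxn1, which encodes the antioxidant enzyme sulfiredoxin, 4.01-fold. Immediate early genes had 5 of 20 higher (mean 0.573, camera adjusted p = 1.97e-06), with Egr1, a transcription factor, up 6.16-fold, and adjusted p = 0.118 with an estimated correlation. Lysosomal genes had 12 of 49 higher and 0 lower (mean 0.307, adjusted p = 0.0524 with an estimated correlation). Oxidative phosphorylation genes had 0 higher and 4 lower of 67 (mean -0.122, camera adjusted p = 0.00264, and adjusted p = 0.653 with an estimated correlation). Camera called 15 lists, 5 of them with an estimated correlation.

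At 6 months, 7 of the 10 rises and 5 of the 9 falls named here were also named at 4 months. Eda2r, Ncam1 and the glucose transporter gene Slc2a1 among the rises were not, nor were Kcnn2, Amd2, Pfkfb3 and Ybx2 among the falls. A gene not named at 4 months may still have differed then, and Eda2r and Ncam1 were called at every age. Ncam1 lay at 9.314 to 9.673 in Gaa-/- and at 6.716 to 6.995 in WT muscle at 4 months. Mt2 rose 23.8-fold (log2 4.57 ± 0.28), Rrad 11.3-fold (log2 3.50 ± 0.30), Mt3 9.67-fold, Serpinb1a 8.47-fold, Map1a 8.3-fold, Eda2r 7.64-fold, Klf5 7.35-fold, Ncam1 6.05-fold, Mt1 5.93-fold and Slc2a1 4.99-fold. Aqp4 fell at least 11.3-fold (log2 -3.50 ± 0.21), Mettl21c 5.48-fold, Mstn 4.9-fold, Mss51 4.74-fold and Slc15a5 4.08-fold. The potassium channel gene Kcnn2 changed by -2.00, Amd2, an enzyme of polyamine synthesis, by -1.88, Pfkfb3, which makes an activator of glycolysis, by -1.82 and the RNA-binding Ybx2 by -1.82. None of these genes overlapped between genotypes in the 4 against 4 arrays, as the naming rule required, with adjusted p from 5.43e-16 (Map1a) to 4.96e-06 (Kcnn2). The count was 1226 genes, 688 higher and 538 lower, with 142 rises and 69 falls of at least 2-fold. After median-centring the calls were 556 higher and 592 lower, and fitted on the 8 arrays of 6 months alone the count was 771.

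The circadian clock list fell at 6 months, with 8 of 17 members lower and 0 higher (mean -0.397, adjusted p = 0.0245 with an estimated correlation). Nr1d1, a repressor of the clock loop, changed by -1.03 ± 0.17 and Per3 by -1.03 ± 0.18. Endothelial markers fell (2 of 13 lower, mean -0.266, adjusted p = 0.00531 with an estimated correlation), including Flt1 at -0.52 and the cadherin gene Cdh5 at -0.41. The neuromuscular list had 9 members higher and 1 lower (mean 0.634, adjusted p = 0.000265 with an estimated correlation). Macrophage markers (15 of 23 higher, mean 0.818) and MHC class II genes (5 of 6 higher, mean 0.902) each had adjusted p = 0.0189 with an estimated correlation, with Fcgr3, an Fc receptor, up 2.89-fold and H2-Eb1 up 2.59-fold. Glycolysis and glucose uptake had 2 higher and 8 lower of 17 (mean -0.217, camera adjusted p = 5.37e-05, and adjusted p = 0.172 with an estimated correlation). Camera called 18 lists, 5 of them with an estimated correlation.

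At 9 months, Mt2 rose 15.5-fold (log2 3.95 ± 0.28), Map1a 8.88-fold (log2 3.15 ± 0.14) and Ncam1 8.46-fold (log2 3.08 ± 0.14). Serpinb1a rose 7.92-fold, Eda2r 7.47-fold, Ttc9 6.5-fold, Plekho1 5.69-fold, Cyfip2, a member of an actin-regulating complex, 5.57-fold, the secreted protease inhibitor Serpina3n 5.41-fold and Cers6 4.83-fold. Aqp4 fell at least 7.25-fold (log2 -2.86 ± 0.21), Slc15a5 5.53-fold, the methyltransferase gene Mettl21e 5.4-fold, Mss51 4.92-fold and Mstn 4.54-fold. Tlcd3b changed by -2.16, Mettl21c by -1.98, Ybx2 by -1.87 and Lrtm1 by -1.80. No value overlapped between the genotypes for these genes, as the naming rule required, with adjusted p from 1.47e-16 (Map1a) to 1.3e-05 (Mettl21e). The test called 2299 genes, 1566 higher and 733 lower, and 211 rises and 43 falls reached 2-fold. Array spread was narrower in WT at 9 months (1.843 ± 0.0452, mean ± SD, n = 4) than in WT at 1.5, 4 and 6 months (1.933 ± 0.0386, 1.966 ± 0.0456 and 1.933 ± 0.0101) and than in Gaa-/- at 9 months (1.914 ± 0.0265). After a second quantile normalization the calls at 9 months were 1385 higher and 1125 lower, and with the array spread as a covariate, an alternative added after the data were seen, 785 higher and 546 lower. From the 8 arrays of 9 months alone 1031 genes were called.

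**Figure D2:**
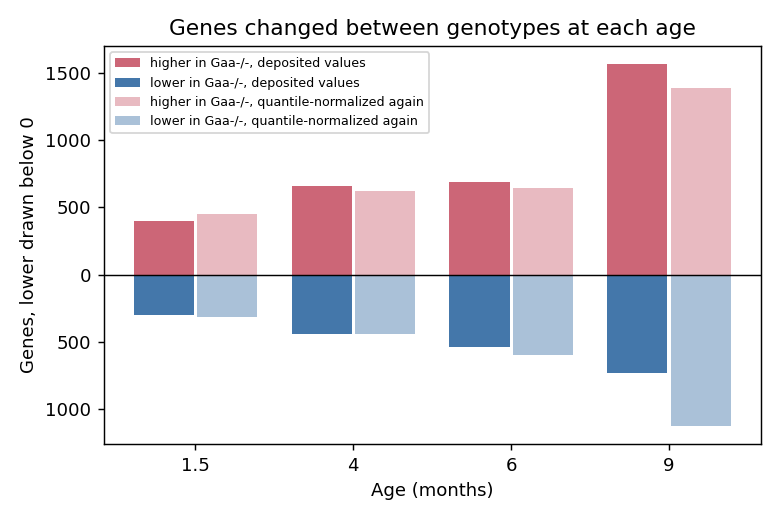
Number of genes changed between genotypes at each age in months (adjusted p under 0.05, n = 4 per group), with genes higher in Gaa-/- drawn above 0 and genes lower below 0, for the deposited values and after a second quantile normalization. At 9 months the deposited values gave 1566 higher and 733 lower, and the quantile-normalized values 1385 higher and 1125 lower.

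Lysosomal genes had 24 of 49 members higher and 0 lower at 9 months (mean 0.442, camera adjusted p = 7.22e-14, and adjusted p = 0.0735 with an estimated correlation). Hexa, a subunit of the lysosomal enzyme hexosaminidase A, rose 4.14-fold and the lysosomal membrane protein gene Lamp1 1.9-fold. Macrophage markers had 16 of 23 higher at that age (mean 0.767, adjusted p = 0.0849 with an estimated correlation) and proteasome subunits 16 of 30 (mean 0.363, adjusted p = 0.123 with an estimated correlation). Fatty acid genes were higher in Gaa-/- at 9 months, with 7 of 22 higher and 14 higher adjusted over the list alone (mean 0.357, camera adjusted p = 4.25e-06, and adjusted p = 0.28 with an estimated correlation). The fatty acid-binding protein gene Fabp3 rose by 0.75 ± 0.16 and the acyl-CoA dehydrogenase gene Acadl by 0.57 ± 0.12. Glycogen genes had 2 higher and 8 lower of 20 (mean -0.205, adjusted p = 0.0735 with an estimated correlation). The neuromuscular list, with 8 higher and 1 lower of 19 and a mean of 0.597, was the 1 list of the 17 called by camera that held with an estimated correlation (adjusted p = 0.00404). Oxidative phosphorylation genes had 6 higher and 1 lower of 67 (mean 0.121, camera adjusted p = 0.00795, adjusted p = 0.692 with an estimated correlation), and their mean was -0.00539 after a second quantile normalization and -0.023 with the array spread as a covariate.

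**Figure D3:**
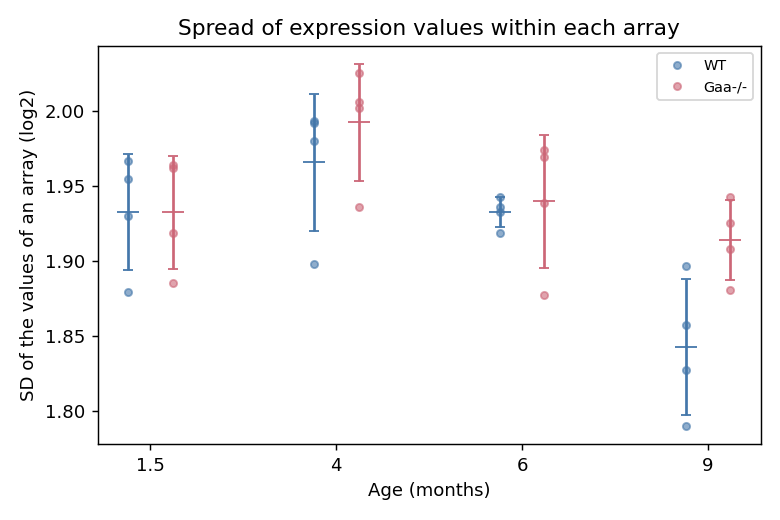
Standard deviation of the log2 values of each array by age in months, with 1 point per array and the mean with SD (n = 4) for WT and Gaa-/-. The WT arrays of 9 months had a mean of 1.843 and the Gaa-/- arrays of 9 months a mean of 1.914.

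Averaged over all 4 ages, a small set of genes differed strongly between genotypes. Mt2 rose 16.4-fold (log2 4.04 ± 0.14), Mt3 8-fold, Mt1 4.84-fold, Map1a 7.9-fold (log2 2.98 ± 0.072), Serpinb1a 7.58-fold, Eda2r 6.61-fold, Rrad 6.31-fold, Ncam1 5.64-fold (log2 2.50 ± 0.0696), Klf5 5.28-fold and Ttc9 4.57-fold. Aqp4 fell at least 7.44-fold (log2 -2.90 ± 0.10), Mettl21c 4.39-fold, Mss51 3.77-fold and Mstn 3.52-fold. Amd2 changed by -1.59, Mettl21e by -1.59, Slc15a5 by -1.58, Tmem100 by -1.56 and Cyp4f39 by -1.45. These genes kept 1 sign at all 4 ages, as the naming rule required, with adjusted p from 1.15e-24 (Map1a) to 2.82e-08 (Mettl21e). In this average over 16 against 16 arrays, 3768 of 19291 genes changed, 2069 higher and 1699 lower, and with the array spread as a covariate the calls were 1843 higher and 1964 lower. Most changes were small: the median absolute log2 difference of the called genes was 0.304, and 117 rises and 37 falls reached 2-fold.

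Genes of the lysosome rose together over all ages. Of 49 measured lysosomal hydrolases and membrane proteins, 27 rose and 0 fell (29 and 0 adjusted over the list alone, mean log2 difference 0.298, camera adjusted p = 1.68e-15, and 0.0305 with an estimated correlation). Hexa rose 2.85-fold (log2 1.51 ± 0.0689), the tetraspanin gene Cd63 2.01-fold, Lamp1 1.54-fold and the protease gene Lgmn 1.76-fold. Of 18 subunits of the V-ATPase, the proton pump that acidifies lysosomes, 9 rose and 0 fell (10 and 0 adjusted over the list alone, mean 0.235, camera adjusted p = 1.25e-05), including Atp6v1a (0.55 ± 0.0661), Atp6v0a1 (0.52), Atp6ap2 (0.51) and Atp6v0d1 (0.38). The V-ATPase list had adjusted p = 0.102 with an estimated correlation. Autophagy machinery had 7 of 42 higher and 3 lower (8 and 3 adjusted over the list alone, mean 0.0647, camera adjusted p = 0.0769). Its receptor gene Sqstm1 rose 1.86-fold, Map1lc3a changed by 0.48, Gabarap by 0.33 and Bnip3 by -0.33. Macrophage markers moved in the same direction as the lysosomal genes, with 19 of 23 higher (mean 0.692).

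**Figure D4:**
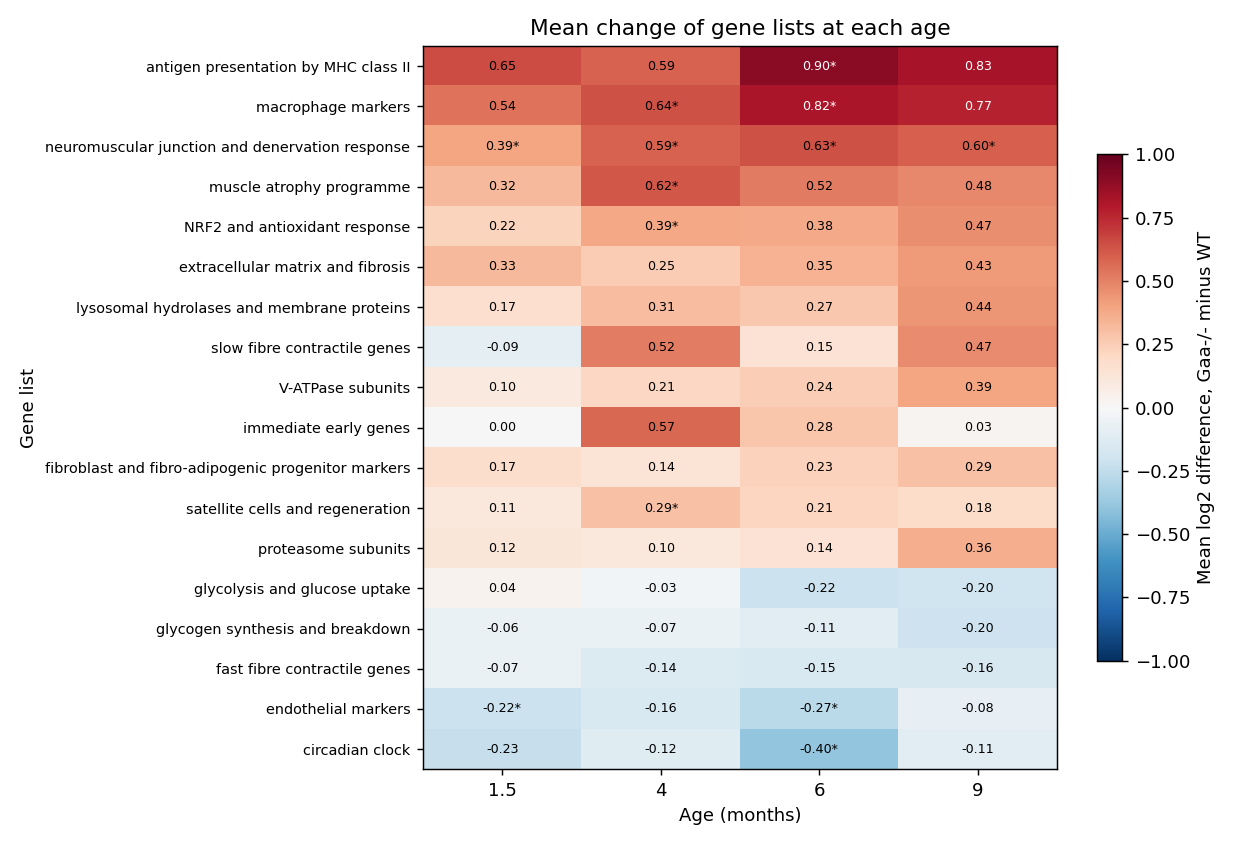
Mean log2 difference (Gaa-/- minus WT, colour and number) of the 18 gene lists called by camera over all ages, shown at each age in months, with a star where the adjusted p with an estimated correlation was under 0.05. The neuromuscular list has a star at all 4 ages, with means from 0.393 to 0.634.

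More genes of glucose metabolism fell than rose over all ages, and neither list held with an estimated correlation. Of 20 genes of glycogen synthesis and breakdown, 2 rose and 8 fell (3 and 8 adjusted over the list alone, mean -0.111, camera adjusted p = 0.00657, and adjusted p = 0.092 with an estimated correlation). The phosphorylase kinase genes Phkg1 (-0.79 ± 0.0448) and Phkb (-0.43) and the phosphoglucomutase gene Pgm1 (-0.39) fell, while Gbe1, the glycogen branching enzyme, rose 1.79-fold. In glycolysis and glucose uptake, 2 of 17 genes rose and 8 fell (2 and 9 adjusted over the list alone, mean -0.102, camera adjusted p = 0.00409, and adjusted p = 0.345 with an estimated correlation). Slc2a1 rose 3.63-fold and the hexokinase gene Hk1 1.68-fold, whereas Pfkfb3 fell 2.43-fold and the glycerol phosphate dehydrogenase gene Gpd1 1.73-fold. Oxidative phosphorylation had 6 of 67 higher and 10 lower (10 and 10 adjusted over the list alone, mean -0.0208, camera adjusted p = 0.693), with Cox6a2 at -0.36, Sdhc at -0.31, Ndufa3 at -0.28 and Ndufb10 at 0.26. Fatty acid uptake and oxidation had 1 of 22 higher and 4 lower (the same counts adjusted over the list alone, mean -0.0415, camera adjusted p = 0.374), with Lpl at -0.46, Acadm at -0.43, Cpt1b at -0.18 and Mlycd at 0.33.

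Among muscle genes, those of the neuromuscular junction and denervation response rose most clearly. Of 19, 12 rose and 1 fell (14 and 2 adjusted over the list alone, mean 0.553, camera adjusted p = 2.96e-11, and 0.000243 with an estimated correlation), including Ncam1, the acetylcholine receptor subunits Chrnd (4.06-fold) and Chrna1 (2.24-fold) and the transcription factor Runx1 (2.23-fold). The member that fell was Dach2, a transcription cofactor (-0.99 ± 0.11), chosen after its values were seen. Fast fibre genes had 0 of 15 higher and 7 lower (0 and 7 adjusted over the list alone, mean -0.13, camera adjusted p = 0.000774, and adjusted p = 0.092 with an estimated correlation), with Actn3 at -0.41, the calcium buffer gene Pvalb at -0.37, Mylk2 at -0.38 and Casq1 at -0.36. Slow fibre genes had 5 of 13 higher and 1 lower (6 and 1 adjusted over the list alone, mean 0.261, camera adjusted p = 0.0399), led by Myoz2 (0.69), Casq2 (0.58) and the calcium pump gene Atp2a2 (0.39), with Myl3 lower (-0.24). That list had adjusted p = 0.349 with an estimated correlation and 0.0697 after a second quantile normalization, and Myl3 had 0.0875 with the array spread as a covariate. Calcium handling and excitation-contraction coupling went both ways, with 5 of 18 higher and 7 lower (5 and 8 adjusted over the list alone, mean 0.0217, median -0.0922, camera direction down with adjusted p = 0.477). There the calcium channel subunits Cacnb1 (0.94) and Cacng1 (0.91) and sarcolipin, Sln (0.95), rose, and the junctophilin gene Jph1 (-0.76) fell.

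The satellite cell and regeneration list had 7 of 18 higher and 1 lower (10 and 1 adjusted over the list alone, mean 0.198, camera adjusted p = 0.005, and adjusted p = 0.0757 with an estimated correlation). Mymk, needed for myoblast fusion, rose 2.03-fold, with Ankrd1 at 0.75, the integrin gene Itga7 at 0.36 and myogenin, Myog, at 0.35. The atrophy list had 7 of 14 higher and 1 lower (7 and 2 adjusted over the list alone, mean 0.487, camera adjusted p = 0.002), and adjusted p = 0.104 with an estimated correlation and 0.198 on ranks. Its median was 0.172, and its largest changes were Mt2, Mt1, the translation repressor gene Eif4ebp1 (2.07-fold) and, lower, Mstn. The muscle ubiquitin ligase genes Trim63 (0.82 ± 0.085) and Fbxo32 (0.39 ± 0.10), both chosen after their values were seen, also rose. Proteasome subunits had 13 of 30 higher and 0 lower (18 and 0 adjusted over the list alone, mean 0.182, camera adjusted p = 1.72e-08, and adjusted p = 0.142 with an estimated correlation), with Psmd6 at 0.59, Psmd11 at 0.42, Psma7 at 0.43 and Psmb1 at 0.27.

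Markers of macrophages and of antigen presentation rose over all ages. Of 23 macrophage markers, 19 rose and 0 fell (20 and 0 adjusted over the list alone, camera adjusted p = 1.55e-17, and 0.0175 with an estimated correlation), with Lyz2 up 3.21-fold (log2 1.68 ± 0.12), Mpeg1 3.34-fold, Cybb, a subunit of the phagocyte oxidase, 2.19-fold and Fcgr3 2.1-fold. Of 6 MHC class II genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone, mean 0.744, camera adjusted p = 1.1e-08, and 0.0175 with an estimated correlation), with H2-Eb1 up 2.3-fold, H2-Aa at 0.88, H2-Ab1 at 0.85 and H2-DMb1 at 0.77. T cell markers had 1 of 11 higher (Cd28, 0.36; mean 0.0851, camera adjusted p = 0.291). B cell markers had 1 of 7 lower (Pax5, -0.27, with 0.146 when the array spread was a covariate; mean -0.119, camera adjusted p = 0.291). Neutrophil markers had 1 of 10 higher, Retnlg (0.76), and 1 lower, Mmp9 (-0.32, with 0.0613 when the array spread was a covariate), and the list had a mean of 0.104 (2 and 1 adjusted over the list alone, camera adjusted p = 0.452). The T and B cell counts were the same adjusted over the list alone.

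Extracellular matrix genes had 14 of 25 higher and 0 lower (16 and 0 adjusted over the list alone, mean 0.339, camera adjusted p = 3.44e-09, and adjusted p = 0.092 with an estimated correlation). Timp1 rose 4.1-fold, with Thbs1, a matrix glycoprotein, at 1.04, the growth factor gene Tgfb1 at 0.70 and the collagen gene Col6a3 at 0.70. Fibroblast and fibro-adipogenic progenitor markers had 6 of 12 higher and 1 lower (8 and 2 adjusted over the list alone, mean 0.208, camera adjusted p = 0.005, and adjusted p = 0.214 with an estimated correlation), with the proteoglycan lumican, Lum, up 2.03-fold, Mfap5 at 0.61, the laminin gene Lamb1 at 0.55 and Clec3b at -0.76. Endothelial markers fell, with 0 of 13 higher and 4 lower (0 and 7 adjusted over the list alone, mean -0.18, camera adjusted p = 0.00173, and 0.0175 with an estimated correlation), namely Flt1 (-0.35) and Kdr (-0.24), both receptors of vascular endothelial growth factor, Cdh5 (-0.25) and the transcription factor Sox17 (-0.32). Smooth muscle and pericyte markers had 1 of 10 higher, Cspg4 (0.77), and 2 lower, Kcnj8 (-0.33) and Rgs5 (-0.24, lost with array weights at 0.0728); the list had a mean of 0.0886 (5 and 2 adjusted over the list alone, camera adjusted p = 0.291). Schwann cell markers had 1 of 9 higher, Egr2 (0.34), and 3 lower, Cldn19 (-0.25), Sox10 (-0.21) and Ncmap (-0.18), with a mean of -0.0849 (1 and 4 adjusted over the list alone, camera adjusted p = 0.309). The calls of these 3 genes were lost with the array spread as a covariate (0.0787, 0.103 and 0.154). Adipocyte markers had 0 of 9 changed (mean -0.0438, camera adjusted p = 0.719) and blood cell markers 0 of 5 (mean -0.0839, camera adjusted p = 0.54), also adjusted over the list alone. Tendon markers had 1 of 8 higher, the transcription factor Scx (0.49), and 1 lower, Fmod (-0.80), with a mean of -0.229 (1 and 2 adjusted over the list alone, camera adjusted p = 0.509).

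Of the stress and signalling lists, the NRF2 and antioxidant response rose, with 11 of 18 higher and 3 lower (12 and 3 adjusted over the list alone, mean 0.363, camera adjusted p = 1.08e-07, and 0.0305 with an estimated correlation). Srxn1 rose 3.23-fold (log2 1.69 ± 0.0818), the quinone reductase gene Nqo1 2.92-fold and the glutathione peroxidase gene Gpx1 1.61-fold, while Gpx3 changed by -0.71. The integrated stress and unfolded protein response had 6 of 19 higher and 4 lower (6 and 4 adjusted over the list alone, mean 0.028, camera adjusted p = 0.452). Its transcription factor gene Xbp1 rose (0.79), while Atf4 (-0.57), Atf5 (-0.42) and Chac1 (-0.95) fell. Circadian clock genes had 1 of 17 higher and 7 lower (2 and 9 adjusted over the list alone, mean -0.216, camera adjusted p = 0.005, and adjusted p = 0.102 with an estimated correlation), with Nr1d1 at -0.77, Hlf at -0.72, Nr1d2 at -0.30 and Per3 at -0.38. Immediate early genes had 7 of 20 higher and 2 lower (8 and 2 adjusted over the list alone, mean 0.221, camera adjusted p = 0.049), with Egr1 up 3.72-fold, Atf3 at 0.76, Junb at 0.73 and Nr4a1 at -0.62. The immediate early list had adjusted p = 0.522 with an estimated correlation and 0.119 after a second quantile normalization, and its call was lost without 19 of the 32 samples, each left out in turn. Interferon response genes had 1 of 19 lower, Usp18 (-0.26; mean -0.0668, camera adjusted p = 0.452), and cell cycle genes had 0 of 19 changed (mean 0.0206, camera adjusted p = 0.69), with the same counts adjusted over the list alone. Over all ages camera called 18 of the 33 lists, 13 higher and 5 lower, fry called 22, and 6 held with an estimated correlation.

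Genes changed at every age numbered 294, 229 higher and 65 lower, against 0.0395 and 0.00728 given by the product of the shares. That product treats the calls at different ages as independent, although 1 estimate of the spread per gene served all ages, so it may understate overlap without a shared effect. The 294 genes included Map1a, Mt2, Serpinb1a, Ncam1 and Eda2r among the rises and Gaa, Aqp4 and Mstn among the falls. Of the 3237 genes called at any age, 2084 were called at 1 age and 19 had calls of both signs. Genotype differences were related between ages across genes, which are not independent replicates. Pearson's r was 0.669 between 4 and 6 months (Spearman's rho 0.426), 0.596 between 4 and 9 months (0.416), 0.568 between 6 and 9 months (0.355) and 0.566 between 1.5 and 4 months (0.377). The lowest were 0.515 between 1.5 and 6 months (0.314) and 0.395 between 1.5 and 9 months (0.222). Calls at 4 and 6 months shared 429 higher genes (23.4 by the product of the shares) and 259 lower genes (12.4 by the product), with 0 of opposite sign. Calls at 1.5 and 9 months shared 298 higher genes (32.6 by the product) and 86 lower genes (11.4 by the product), with 15 of opposite sign.

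The interaction test asked whether the genotype difference itself changed with age, and 106 genes passed. Slc15a5 rose in WT from 6.865 ± 0.075 at 1.5 months to 8.824 ± 0.31 at 4 months (mean ± SD, n = 4) and was 6.747 ± 0.26 and 7.125 ± 0.22 in Gaa-/- at these ages (interaction adjusted p = 6.97e-05). Serpina3n differed by 0.65 at 1.5 months and 2.44 at 9 months (interaction adjusted p = 8.74e-05). Cyfip2, at 0.26 and not past the test at 1.5 months, rose by 1.41 at 4 months and 2.48 at 9 months (interaction adjusted p = 0.000283). Mybph was 8.643 ± 0.61 in WT at 1.5 months and 5.565 ± 0.13 at 4 months, against 9.167 ± 0.25 and 8.263 ± 0.34 in Gaa-/- (interaction adjusted p = 0.00173). The calcium-binding protein gene Casq2 rose by 1.75 at 9 months and had no call at 1.5 months (adjusted p = 1) (interaction adjusted p = 0.00144). Fxyd6, a regulator of the sodium pump, went from -0.48 to 1.05 between these ages, the receptor gene Crhr2 from -0.67 to 0.33 (adjusted p = 0.0671 at 9 months) and the diacylglycerol kinase gene Dgka from -0.55 to 0.61, with interaction adjusted p of 0.000853, 0.0018 and 0.0019. Clip4 and Ncam1 each had 0.00201. Leaving out single samples moved the count between 38, without replicate 3 of Gaa-/- at 1.5 months, and 201, without replicate 2 of Gaa-/- at 9 months. Without the 9-month samples, an alternative added after the data were seen, the count was 24.

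The difference at 9 months minus that at 1.5 months passed for 282 genes, 216 with a higher and 66 with a lower value at 9 months. Slc15a5 changed by -2.35 ± 0.27, Cyfip2 by 2.22 ± 0.27, Serpina3n by 1.78 ± 0.22, Fxyd6 by 1.53 ± 0.20, Dgka by 1.16 ± 0.16, Ncam1 by 1.38 ± 0.20 and Clip4 by 0.95 ± 0.14. The mitochondrial isocitrate dehydrogenase gene Idh2 changed by 2.70 ± 0.39, the fibroblast growth factor receptor-like Fgfrl1 by 1.11 ± 0.16 and Sln, an inhibitor of the muscle calcium pump, by 1.98 ± 0.29, and adjusted p-values of these 10 genes ran from 1.25e-05 (Slc15a5) to 0.000288 (Sln). Fatty acid genes had the largest shift of the 33 lists in this contrast, with 11 of 22 higher and 0 lower (18 and 0 adjusted over the list alone, mean 0.745, camera adjusted p = 1.06e-20), and adjusted p = 0.105 with an estimated correlation. Acadl changed by 0.94 ± 0.17 and Hadh, a dehydrogenase of fatty acid oxidation, by 1.01 ± 0.18. Slow fibre genes had 3 of 13 higher (mean 0.559, adjusted p = 0.394 with an estimated correlation), among them Casq2 and Myoz2 (1.53). Fast fibre genes had 3 of 15 lower (mean -0.0923, adjusted p = 0.351 with an estimated correlation), including Actn3 (-0.54, with 0.0865 when the array spread was a covariate). Camera called 11 lists and 0 held with an estimated correlation, where 3 of the 33 had an unadjusted p under 0.05. Leaving out single samples gave counts from 106, without replicate 3 of Gaa-/- at 1.5 months, to 635, without replicate 2 of Gaa-/- at 9 months. With the array spread as a covariate 138 genes were called, 76 higher and 62 lower. After a second quantile normalization 159 were higher and 112 lower.

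Within WT, 3670 genes changed with age, 1329 higher and 2341 lower at 9 than at 1.5 months. The largest falls included the matrix protein gene Postn at -2.54, the actin-binding Nexn at -3.23, Mybph at -2.41, the collagen gene Col3a1 at -1.93 and the leucine-rich matrix protein genes Aspn (-2.26) and Kera (-2.08). The Wnt antagonist Sfrp4 changed by -1.99, Hmgn5 by -1.95, the condensin gene Smc4 by -1.92 and the muscle LIM protein gene Csrp3 by -1.90. Genes that rose included Slc15a5 (3.88-fold), Neto2 (1.45), Prune2 (1.31), the urocortin gene Ucn (1.30), Slc24a2, a calcium exchanger (1.15), the bicarbonate transporter gene Slc4a4 (1.09), Defb7 (1.08), Atp13a5 (1.04) and the clock gene Arntl (1.05). Adjusted p-values of the F-test for the genes named here ran from 9.4e-10 (Mybph) to 0.025 (Csrp3). With the array spread as a covariate 981 genes were called, 483 higher and 498 lower. With that covariate the calls ended for Postn (-2.23, adjusted p = 0.0857), Nexn (-2.23, 0.11), Sfrp4 (-1.50, 0.0626), Csrp3 (-1.29, 0.0514), Hmgn5 (-1.28, 0.266), Smc4 (-0.80, 0.392) and Kera (-0.73, 0.431), and Csrp3 also had 0.0567 with the trended prior. After a second quantile normalization the calls were 1724 higher and 1675 lower, without the 9-month samples the count was 234, and without replicate 1 of WT at 9 months it was 2208.

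Within Gaa-/-, 903 genes changed with age, 467 higher and 436 lower at 9 than at 1.5 months, and after median-centring the calls were 407 higher and 459 lower. Cyfip2 rose 4.73-fold, Serpina3n 4.05-fold, Sln 2.9-fold, and the kallikrein gene Klk1b22 by 1.59, Prelid2 by 1.25, Zfp641 by 1.17, the potassium channel gene Kcnn3 by 1.14, the complement gene C7 by 1.13 and Map1b, a microtubule-associated protein, by 1.13. Mettl21e fell 9.47-fold, with Mybph at -1.98, the Wnt antagonist Frzb at -1.96, the chaperone clusterin, Clu, at -1.91, Aqp4 at -1.90, Lrtm1 at -1.81, Mstn at -1.75, and the collagen genes Col1a1 and Col3a1 at -1.77 and -1.75. Adjusted p-values of the F-test for these genes ran from 3.22e-10 (Serpina3n) to 0.0101 (Klk1b22). Whether a gene changed differently with age in the genotypes is the question of the interaction test, which passed for 106 genes. With array weights 2098 genes were called, without the 9-month samples 299, and leaving out single samples gave 557, without replicate 3 of Gaa-/- at 1.5 months, to 1469, without replicate 1 of Gaa-/- at 4 months.

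Around Gaa, 27 of the 100 nearest tested genes (50 on each side in gene order) changed over all ages, or 27%, against 19.5% of the other genes. The odds ratio was 1.53 (95% interval 0.943 to 2.41), with p = 0.0753 by Fisher's exact test. The changed neighbours included the septin gene Septin9 (0.78 ± 0.0507), Hgs, which encodes an endosomal sorting protein (0.63 ± 0.0609), Nploc4 (0.43) and the endoplasmic reticulum isomerase gene P4hb (0.36), all higher, and Cbr2 (-0.85 ± 0.10) and Faap100 (-0.42), both lower.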

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

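The tests of the array spread were chosen after the result was seen, and the other tests of this part were chosen before.

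The genotype difference itself changed with age for 106 genes by the interaction test, and for 282 genes between 9 and 1.5 months. Between these ages the difference changed by -2.35 for Slc15a5, 1.78 for Serpina3n, 2.22 for Cyfip2, 1.53 for Fxyd6, 1.75 for Casq2, 0.997 for Crhr2, 1.16 for Dgka, 0.949 for Clip4, 1.38 for Ncam1, 2.7 for Idh2, 1.11 for Fgfrl1 and 1.98 for Sln. Mybph passed the interaction test because it differed most at 4 months, and its difference between 9 and 1.5 months was 0.432 (adjusted p = 0.592). By fry, the lists with a difference between 9 and 1.5 months were fatty acid uptake and oxidation (mean 0.745, adjusted p = 0.000461), slow fibre genes (0.559, 0.047), fast fibre genes (-0.0923, 0.000461), glycogen synthesis and breakdown (-0.141, 0.0312) and glycolysis and glucose uptake (-0.239, 0.0312). None of these 5 lists held with an estimated correlation, where their adjusted p ran from 0.105 to 0.394.

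Among the 788 probe sets without a gene in the platform table, 155 changed over all ages (19.7%), 91 higher and 64 lower. They stand outside every count of genes in the report.

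In 15 of 280 tests of a group of 4 arrays, 1 array stood apart from the other 3 by Dixon's test, and chance gives about 1 in 20. The array spread of replicate 3 of WT at 4 months was 1.898, against 1.98 to 1.993 in the others. Replicate 1 of Gaa-/- at 6 months had the highest neutrophil mean of its group (6.033 against 4.508 to 4.685) and the highest tendon mean (7.432 against 6.102 to 6.231). Replicate 2 of WT at 6 months stood out in immediate early genes (7.505 against 6.6 to 6.672), and replicate 4 of Gaa-/- at 6 months in blood cell markers (5.776 against 6.043 to 6.075). At 9 months, replicate 2 of Gaa-/- stood out in T cell markers (5.288 against 4.909 to 4.971), replicate 4 in MHC class II genes (7.09 against 6.889 to 6.924) and replicate 3 in the neuromuscular list (6.934 against 7.1 to 7.12). At 1.5 months, replicate 3 of Gaa-/- was lowest in the atrophy list (8.115 against 8.256 to 8.28) and in proteasome subunits (8.935 against 9.052 to 9.056), and replicate 2 highest in oxidative phosphorylation (10.55 against 10.48 to 10.49). At 4 months, replicate 4 of Gaa-/- was highest in the neuromuscular list (7.187 against 7.098 to 7.11), replicate 1 of Gaa-/- lowest in V-ATPase subunits (7.281 against 7.561 to 7.618) and replicate 1 of WT lowest in the stress response list (6.846 against 6.979 to 7). Replicate 1 of WT at 6 months was lowest in V-ATPase subunits (7.226 against 7.27 to 7.278).

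Calls at 9 months were more often rises (68.1%) than at the other ages (56.1% to 59.7%). After a second quantile normalization, which gives every array the same spread, the share at 9 months was 55.2%, against 51.7% to 58.7% at the other ages. With the array spread as a covariate it was 59%, against 50.3% to 52.7%, and after median-centring, which leaves the spread as it was, 71% against 48.4% to 68.6%. The excess of rises and the narrower spread of the WT arrays of 9 months cannot be told apart, because these corrections disagree and the spread coincides with that group. In those arrays the median gene of the dimmest of 5 equal classes lay 0.1 above, and that of the brightest class -0.2 from, its level at the other WT ages, against 0.061 and -0.059 in Gaa-/- at 9 months.

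Lysosomal genes rose by 0.298 ± 0.035 over all ages as a list mean, and macrophage markers by 0.692 ± 0.071. With the macrophage mean of each sample as a covariate, the lysosomal difference was 0.0625 ± 0.057, so more macrophages may account for much of the rise. The 2 lists share 0 members, and Lyz2, an abundant macrophage transcript, ran from 5.819 to 7.818 in WT and from 7.874 to 9.851 in Gaa-/- muscle. The same covariate took the V-ATPase difference from 0.235 ± 0.042 to 0.0266 ± 0.081. Its slope rests on differences among arrays of the same group, where the lysosomal and macrophage means had r = 0.696. Anything else that moves both means together among those arrays enters the slope too. In the difference between 9 and 1.5 months, camera called the lysosomal list (adjusted p = 2.86e-05) and not the macrophage list (adjusted p = 0.209). With an estimated correlation 0 lists held in that contrast, and whether the 2 time courses differed was not tested. A lysosomal response within muscle fibres therefore stays open and was not tested.

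Changed genes were somewhat more frequent next to Gaa, with an odds ratio of 1.53 (0.943 to 2.41). Sequence of another strain flanking the targeted allele may produce such a pattern, since the mice are labelled as a mix of strains. It was set beforehand that a Fisher p of 0.05 or more would count against this, and the p was 0.0753. That rule was wrong, because the interval reaches 2.41 and a p that misses the threshold excludes nothing. The flanking sequence and no local effect cannot be told apart with 100 neighbours.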

How the results depend on the processing

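The array spread as a covariate and the fit without the 9-month samples were chosen after the result was seen, and the other alternatives before. Unless a construction is named, the cause was not tested.

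Gaa kept its direction and its call with the replicate block, the dim filter, the trended prior, array weights, quantile normalization, median-centring and the array spread as a covariate, with log2 differences without single samples from -3.755 to -3.603 at 1.5 months, -3.641 to -3.455 at 4, -3.872 to -3.626 at 6 and -3.802 to -3.769 at 9 months. Of 431 results of named genes, 420 kept direction and call after a second quantile normalization, 413 with array weights, 416 with the trended prior, 419 after median-centring, 424 with the replicate block and 400 with the array spread as a covariate, and none reversed. Of 198 list results, 186 kept theirs after quantile normalization, 181 on ranks, 165 with fry and 123 with an estimated correlation, where 75 were weaker.

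Counts beyond 1.5 times the reported ones follow, with 2 correlations that moved. A minimum of 1.5-fold, stricter by construction, gave 397, 648, 677 and 1081 genes from 1.5 to 9 months, 534 over all ages, 181 at every age, 1363 with age in WT and 479 in Gaa-/-. An adjusted p under 0.01, also stricter, gave 378, 627, 673 and 1182 genes, 190 at every age, 24 in the interaction, 71 for the 9 minus 1.5 month difference, 1682 with age in WT and 286 in Gaa-/-. Only the samples of an age, fewer by construction, gave 771 at 6 and 1031 at 9 months. The interaction count was 170 without the dimmest genes, 195 with the trended prior and 207 with array weights. Array weights also gave 1136 at 1.5 months, 562 for the 9 minus 1.5 month difference and 2098 with age in Gaa-/-. The array spread as a covariate gave 1331 at 9 months, 138 for that difference and 981 with age in WT. Without the 9-month samples, fewer by construction, the interaction count was 24, and age changed 234 genes in WT and 299 in Gaa-/-. Without the dimmest genes the correlation was 0.597 between 1.5 and 6 months and 0.767 between 4 and 6 months.

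The shares of rises moved with scaling. Quantile normalization gave 1385 higher and 1125 lower at 9 months, 48 and 48 in the interaction, 159 and 112 for the 9 minus 1.5 month difference, and 1724 and 1675 with age in WT. The covariate gave 785 and 546, 41 and 44, 76 and 62, and 483 and 498, and over all ages 1843 and 1964, where falls outnumbered rises. At 4 months median-centring gave 701 and 321 and the covariate 666 and 658. Median-centring turned the majority to falls at 6 months (556 and 592) and with age in Gaa-/- (407 and 459).

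With an estimated correlation, 6 lists passed over all ages, 2 at 1.5, 5 at 4, 5 at 6 and 1 at 9 months, and 0 for the 9 minus 1.5 month difference, where fry and the covariate each gave 5. Oxidative phosphorylation at 9 months reversed to -0.00539 after quantile normalization and -0.023 with the covariate, autophagy at 9 months to -0.00739 with the covariate, and the camera direction of oxidative phosphorylation turned in the 9 minus 1.5 month difference after quantile normalization (mean 0.0128). Near Gaa the odds ratio was 1.6 with 25 genes on each side and 1.31 after quantile normalization. With up to 100 genes on each side it was 1.4, over 170 neighbours, because the chromosome ended within that window.

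Leaving out single samples gave 456 to 652 genes at 1.5 months, 820 to 972 at 4, 926 to 1137 at 6 and 1572 to 2687 at 9 months, 3524 to 4015 over all ages, 228 to 309 at every age, 38 to 201 in the interaction, 106 to 635 for the 9 minus 1.5 month difference, 2208 to 4291 with age in WT and 557 to 1469 in Gaa-/-. Correlations between ages were 0.507 to 0.585, 0.48 to 0.512, 0.301 to 0.454, 0.631 to 0.678, 0.516 to 0.653 and 0.514 to 0.629 for 1.5 and 4, 1.5 and 6, 1.5 and 9, 4 and 6, 4 and 9, and 6 and 9 months. List counts were 16 to 19 over all ages, 10 to 15, 15 to 17, 15 to 19 and 14 to 17 at the 4 ages, and 9 to 12 for the difference. Beyond 1.5 times lay 456 genes without replicate 1 of Gaa-/- at 1.5 months, and 2208 with age in WT without replicate 1 of WT at 9 months. Age in Gaa-/- gave 557 without replicate 3 of 1.5 months, 573 and 1469 without replicates 3 and 1 of 4 months, and 589 without replicate 1 of 9 months. The interaction gave 58 and 38 without Gaa-/- replicates 1 and 3 of 1.5 months, 53, 201, 43 and 58 without replicates 1 to 4 of Gaa-/- at 9 months, 69, 62 and 45 without WT replicates 1, 2 and 4 of 1.5 months, and 53 and 171 without WT replicates 2 and 4 of 9 months. The 9 minus 1.5 month difference gave, in the same order, 179 and 106, then 156, 635, 135 and 138, then 185, 125 and 122, then 141 and 450, and 164 without WT replicate 1 of 9 months.

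The replicate numbers showed no general pairing, since of 16 pairs 3 had a residual correlation over 0.1 and 3 had the same number as best partner. Those 3 were replicates 2 and 3 at 1.5 months (0.213 and 0.296) and replicate 4 at 9 months (0.227). Pairing at 1.5 months is therefore not excluded. The mean of several probe sets changed nothing because each gene had 1, and Xist as a covariate was not run. Signal over background limits dim genes, of which the lowest 30% lay under a mean of 4.72.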

Other observations

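The tests of the array spread in this part were chosen after the result was seen, while the other splits of the samples were chosen before.

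Several further genes of the neuromuscular list differed over all ages, all chosen after their values were seen. Musk, the receptor kinase that organizes the junction, rose by 0.90 ± 0.078, the acetylcholinesterase gene Ache by 0.78 ± 0.069, and the cell cycle inhibitor gene Cdkn1a by 0.92 ± 0.12. Klf15, a transcription factor active in fatty acid metabolism, also chosen after its values were seen, changed by 1.47 between 9 and 1.5 months (adjusted p = 0.00323).

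The fatty acid list difference between 9 and 1.5 months was 0.745 in the deposited values, 0.573 after a second quantile normalization and 0.552 with the array spread as a covariate, past camera in all 3, so the values argue against the narrower spread of the WT arrays of 9 months as its whole cause. The list had adjusted p = 0.105 with an estimated correlation, and chance was not excluded for the number of lists in this contrast. Genes changed with age in WT outnumbered those in Gaa-/- by a ratio of 4.06, and the ratio was 4 after quantile normalization, 1.09 with the array spread as a covariate and 0.783 without the 9-month samples. That ratio and the narrower spread cannot be told apart, because the spread coincides with the WT group of 9 months.

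Other splits of the same samples were counted to ask whether chance can be excluded. For genes changed, chance can be excluded at 1.5 months (1 of 35 splits gave as many, the real one with 700, the highest other with 2), at 4 months (1 of 35, 1099, other 1), at 6 months (1 of 35, 1226, other 4) and at 9 months (1 of 35, 2299, other 1625). The split with 1625 genes exchanged replicate 4 of WT with replicate 2 of Gaa-/- at 9 months, whose Gaa levels of 10.616 and 6.811 match their labels. That WT array had the widest spread of its group (1.8969) and that Gaa-/- array the narrowest of its group (1.8808). The exchange thus ordered the arrays of 9 months by spread, and much of the count there is not separated from the array spread. Of 100 drawn splits, 1 gave as many genes over all ages (3768, other 1), at every age (294, other 0), with age in WT (3670, other 269) and with age in Gaa-/- (903, other 1), and chance can be excluded for each. In the interaction test 1 of 100 also gave as many (106, other 4). Its splits regrouped the ages within each genotype, which also removed changes with age common to both genotypes. They therefore cannot exclude chance for the interaction itself. For the difference between 9 and 1.5 months 2 of 100 splits gave as many, which is within the limit set beforehand for excluding chance. The highest other split called 675 genes against the real 282. A count of this size thus also arose from regrouped ages, and chance is not firmly excluded. What set that split apart was not tested, and the array spread was not separated from it.

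For lists past camera, the real split gave more than any other at 6 months (1 of 35 splits, 18 lists, highest other 17). The same held at 9 months (1 of 35, 17, other 15) and over all ages (1 of 100, 18, other 16). The rule set beforehand was met there, but the margins were narrow and chance is not firmly excluded. Chance cannot be excluded at 1.5 months (2 of 35 splits, 15 lists, highest other 15), at 4 months (3 of 35, 15, other 15) or for the difference between 9 and 1.5 months (23 of 100, 11, other 18). The median of the other splits was 6 to 8.5 lists, so camera with a preset correlation called lists from regrouped samples too. Splits that move few arrays keep part of the real difference, so such calls need not be false. The splits thus cannot tell how often camera calls lists without any effect.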
